A study of Mus musculus with 8 samples.

How the data were processed

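Total RNA of TTE3 cells was extracted with a column kit and treated with DNase, and 5 µg per array entered one-cycle cDNA synthesis and biotin labelling by in vitro transcription, per the labels' protocols. Samples were hybridised to Affymetrix Mouse Expression Array 430A arrays, 1 sample per array. Samples were grouped by the hours at 39 °C in their titles, 0, 6, 12 and 24 h, with 2 numbered samples per time. No label says whether the 2 samples of a time came from separate cultures, so p-values measure only the spread between these samples, which can be technical.

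The deposited values are probe set intensities on a linear scale, from 0.1 to 38130.2. The software and settings that made them are not given in the sources used here. The mean after removing 2% of values at each end was between 500.18 and 500.2 on every array, so the deposited intensities had been scaled to a common mean before they were used here. Whatever changed the total amount of mRNA per cell is therefore not visible. Detection calls were not used here, so no probe set was called present or absent, and signal over background sets a limit for dim genes.

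Precision is limited by 2 arrays per time. Median signals ran from 138 to 154 units. Across probe sets, which are not independent replicates, the 2 arrays of a time correlated with r = 0.9904 at 0 h, 0.9815 at 6 h, 0.9843 at 12 h and 0.9898 at 24 h. Arrays of different times correlated with r between 0.9458 and 0.9786. The first principal component held 44.3% of the variance and ran from -31.8 and -30.4 at 0 h to 27.6 and 28.1 at 24 h. The second held 23.6%, and there the 6 h arrays lay lowest, at -29.3 and -17.7. The ratio of 3' to 5' control signals, a sign of RNA integrity, lay between 1.03 and 1.13 for actin and between 0.717 and 0.805 for Gapdh.

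Of 22626 probe sets left after 64 control probe sets, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 were unnamed here. Symbols were checked through gene identifiers against a RefSeq gene table of assembly GRCm38.p6, used for names only. No gene was named from a probe set with several symbols, which leaves out transferrin, a planned Sertoli gene. Values were taken as log2(intensity + offset), with the 20th percentile of all values, 21.9, as offset, so log2 changes understate those of dim genes. A fold is 2 to the power of such a log2 change. Arrays were used as deposited because their median log2 values lay within 0.14 of each other, under the limit of 0.3 set beforehand. Probe sets with a mean log2 value under the 40th percentile (6.584) were left out, and 13576 remained, 12553 of them with 1 symbol, for 7707 genes.

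All 8 arrays entered 1 linear model with the 4 times as groups, fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend), with 4 residual and 7.22 prior degrees of freedom. Any change over time was tested with the moderated F-test, and the 6 pairs of times with moderated contrasts, 2-sided. P-values were adjusted by Benjamini-Hochberg over the tested probe sets and called at adjusted p below 0.05. Calls refer to this threshold, and values after ± are standard errors of the fit unless SD is named. An adjusted p given with a setting after a called value is that under a setting that ended the call. Ranges over the alternatives, or over the probe sets of a gene, are given where a value moved, or the probe sets differed, by over 1.5-fold.

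Gene lists (27 lists, 1240 entries, of which 823 were tested) were fixed before the data were examined, as were the tests of probe sets, the tests of lists against 0 h, the alternatives and the rule for naming genes. Tests of lists between later times were not part of that plan, nor were the counts of probe sets that moved back after 6 h and their simulations. Lists between later times were run with quantile normalization, median-centred arrays, an estimated correlation and fry as alternatives. The lists were p53 targets, DNA replication, mitosis, cytosolic heat shock, ER stress, ribosome biogenesis and MYC targets, ribosomal proteins, oxidative phosphorylation, glycolysis and lactate, cholesterol synthesis, lysosome, interferon response, secreted inflammatory and senescence factors, NRF2 oxidative stress, immediate early genes, TGF-beta and BMP targets, circadian and growth arrest, histone genes, cell junctions, extracellular matrix and reference genes. Cell type lists were Sertoli, steroidogenic Leydig, peritubular myoid and smooth muscle, germ, macrophage and blood, and endothelial markers. Each gene was represented by its probe set with the highest mean, and lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 27 lists of a comparison; camera with an estimated correlation and fry were alternatives. A median log2 difference of a list between later times is the median over its genes of each gene's own difference. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. Lists share members: 8 of 24 Sertoli markers and 9 of 40 immediate early genes are also on another list. Genes that a sentence calls risen or fallen passed the test over all probe sets; where a count is adjusted over the list alone, the adjustment ran over that list's genes only.

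Genes were named by rule: per comparison with 0 h, the 10 largest rises and 10 largest falls among probe sets with 1 symbol that passed and whose 2 later arrays both lay on the same side of both 0 h arrays, leaving out clone and locus names; 5 each between later times; up to 4 members per list with the largest called change at 24 h, or the 2 brightest where none passed; and Cdkn1a, Mdm2, Ccng1, transferrin, Clu, Pcna, Mki67, Hspa1b and Hsp90aa1 where measured. For the largest changes the probe set with the largest change stands for its gene, and elsewhere the brightest.

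Alternatives were no offset, an offset at the 40th percentile, quantile normalization, median-centred arrays, no filter, a filter at the 60th percentile, no variance trend, only the 2 times compared, the replicate number as a block, 1 probe set per gene, and leaving out each array. With an array left out, the remaining array of its time is assumed to vary like those of the other times. The fit was tested on simulated values for 24 h against 0 h with 200 of 13576 probe sets changed: 40% of log2 changes of 0.5, 88% of 1 and 100% of 2 and of 3 were recovered, and 10 of 174 calls were false. A log2 shift of 0.5 given to the 30 p53 targets was called by camera, and 0 of the other 26 lists were. Genes were simulated as independent, so this does not test false list calls among correlated genes.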

Results

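TTE3 is a mouse testicular Sertoli cell line, made from transgenic mice that carry a temperature-sensitive large T-antigen of simian virus 40. Sertoli cells are the somatic cells of the seminiferous tubule that nurse developing germ cells. The T-antigen drives proliferation and binds p53, and it is inactive at the nonpermissive temperature of 39 °C. Gene expression was measured after 0, 6, 12 and 24 h at 39 °C, with 2 samples per time and 8 arrays in all.

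Expression moved widely over the 24 h, with p53 target genes higher at every later time, heat shock genes rising first and falling back, and ribosome biogenesis genes lower from 12 h on. In the moderated F-test over the 4 times, 5447 of 13576 tested probe sets changed. Of these, 1510 (27.7%) had their largest change from 0 h as a rise at 24 h and 1403 (25.8%) as a fall at 24 h. The largest change was at 6 h for 589 risen and 779 fallen probe sets and at 12 h for 549 and 617. Without 0 h replicate 1 the F-test called 3303 probe sets, and without 0 h replicate 2 it called 3383. Samples after 0 h differ from it in temperature and in time, and T-antigen state follows temperature, so the comparisons with 0 h do not separate these.

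**Figure D1:**
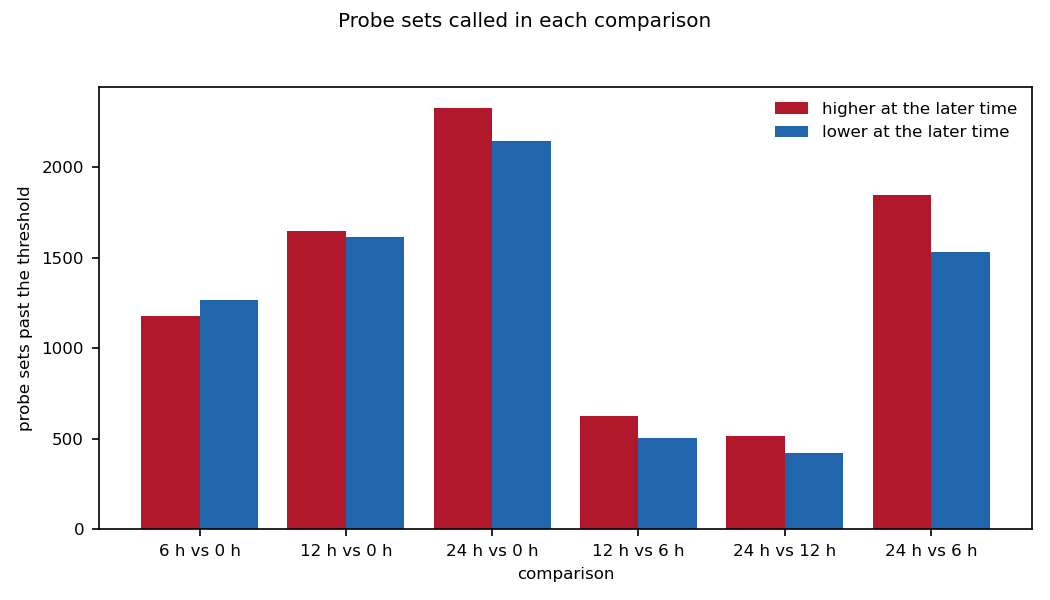
Number of probe sets past the threshold (y axis) in each of the 6 comparisons of 2 times (x axis), with red bars for probe sets higher and blue bars for those lower at the later time. The comparison of 24 h with 0 h has the tallest bars, 2326 higher and 2146 lower, and that of 24 h with 12 h the shortest, 512 and 422.

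The first comparison asked what had changed after 6 h at 39 °C. Heat shock genes had the largest named rises: the inducible Hsp70 genes Hspa1a and Hspa1b went from 288 ± 26.4 to 3744 ± 483 and from 871 ± 77.5 to 7697 ± 313 signal units (mean ± SD, n = 2 each), 12.1-fold and 8.66-fold. Both genes are near-identical in sequence, so the split of signal between them is uncertain. The Hsp110 gene Hsph1 rose 9.19-fold. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose 7.22-fold, from 860.1 ± 73.5 to 6332 ± 182. Cirbp, an RNA-binding protein gene known to be induced by cold, fell from 352 ± 6.58 to 25.4 ± 22.7, near the offset of 21.9 units. Its log2 change ran from -3.58 to -2.07 over the alternatives that tested it. That range does not include the fit without an offset, so it understates how far the value depends on the offset.

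In all, 2441 probe sets passed, 1175 higher and 1266 lower, of which 161 rose and 134 fell at least 2-fold. Among the remaining large rises, log2 changes (± SE) were Mmp13 (2.20 ± 0.15), Ccng1 (2.10 ± 0.11), Hspa4 (2.06 ± 0.16), Trp53inp1 (2.05 ± 0.10), Angptl4 (2.04 ± 0.15) and Notch1 (2.0 ± 0.17). Mmp13 encodes a collagenase, Ccng1 cyclin G1, Angptl4 a secreted regulator of lipoprotein lipase and Notch1 a receptor for ligands on neighbouring cells. The Hspa4 probe sets disagreed: of 3 tested, 1 was called in the opposite direction, and the lowest log2 change was -0.51. Large falls included the linker histone gene H1f2 (-2.38 ± 0.14), the splicing factor gene Srsf5 (-2.09 ± 0.12) and the RNA-binding protein gene Hnrnpd (-1.68 ± 0.11). Fstl1 (-1.85 ± 0.11), which encodes follistatin-like 1, Vti1a (-2.47 ± 0.27), Nudcd3 (-1.61 ± 0.20) and Ica1 (-1.60 ± 0.29) fell as well. So did Cacna2d1 (-1.75 ± 0.39, adjusted p = 0.0502 without 0 h replicate 1 and 0.0987 without 0 h replicate 2) and Txnrd3 (-1.55 ± 0.30, adjusted p = 0.054 without 0 h replicate 1).

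The p53 target list rose at 6 h: 19 of 30 rose, 0 fell and 11 did not pass, or 20 and 0 adjusted over the list alone (camera adjusted p = 5.25e-15, adjusted p = 0.0196 with an estimated correlation). Besides Cdkn1a, the p53 ubiquitin ligase gene Mdm2 rose 3.89-fold, a log2 change of 1.96 ± 0.10. Ddit4, which encodes an inhibitor of mTORC1 signalling, rose by 1.78 ± 0.12 and Ephx1, the microsomal epoxide hydrolase gene, by 1.07 ± 0.09 on the log2 scale. In the cytosolic heat shock list, 19 of 37 rose, 3 fell and 15 did not pass, or 20 and 4 adjusted over the list alone (camera adjusted p = 5.18e-08, adjusted p = 0.0374 with an estimated correlation). There the small heat shock protein gene Cryab had a log2 change of 0.72 ± 0.11, Dnajb2 of 1.19 ± 0.15 and Hsp90aa1 a smaller one (0.55 ± 0.10, adjusted p = 0.0518 without 0 h replicate 1). ER stress genes rose too: 18 of 40 rose, 2 fell and 20 did not pass, or 19 and 3 adjusted over the list alone (camera adjusted p = 2.68e-05, adjusted p = 0.0374 with an estimated correlation). The chaperone genes Sdf2l1 (1.61 ± 0.11) and Pdia4 (1.40 ± 0.20) were higher, and the amino acid transporter gene Slc7a5 was lower (-0.77 ± 0.16, adjusted p = 0.0623 without 0 h replicate 1 and 0.0687 without 0 h replicate 2).

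Cholesterol synthesis genes fell at 6 h: 0 of 26 rose, 15 fell and 11 did not pass, or 0 and 18 adjusted over the list alone (camera adjusted p = 8.17e-07, adjusted p = 0.0374 with an estimated correlation). Sqle, encoding squalene epoxidase (-0.63 ± 0.10), and Lss, encoding lanosterol synthase (-0.61 ± 0.12, adjusted p = 0.0719 without 0 h replicate 1), fell. The ribosomal protein list was called upward at a median log2 change of 0.16: 1 of 42 rose, 0 fell and 41 did not pass, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.00442, adjusted p = 0.597 with an estimated correlation). That call ended under several settings, with adjusted p = 0.292 after quantile normalization, 0.217 without 6 h replicate 1 and 0.123 by fry. The median was 0.06 after quantile normalization and 0.05 without 6 h replicate 1. The list means of the 2 arrays at 6 h were 0.26 and 0.07 on the log2 scale relative to 0 h. DNA replication was not called as a list: 10 of 60 rose, 9 fell and 41 did not pass, or 18 and 11 adjusted over the list alone (camera adjusted p = 0.455, but adjusted p = 0.0454 by fry). Neither was mitosis: 2 of 68 rose, 10 fell and 56 did not pass, or 2 and 10 adjusted over the list alone (camera adjusted p = 0.0792, but adjusted p = 0.0142 without a filter, 0.0393 without 6 h replicate 2 and 0.0454 by fry). Pcna, the DNA polymerase clamp, had a log2 change of 0.26 ± 0.09 (adjusted p = 0.061) and the proliferation marker Mki67 of -0.24 ± 0.12 (adjusted p = 0.182). Clu, which encodes the Sertoli product clusterin, was at 0.10 ± 0.15 (adjusted p = 0.681). Without 0 h replicate 1 the number of called probe sets was 836, and without 0 h replicate 2 it was 950. Over the alternatives, among them other offsets, log2 changes ran from -3.27 to -1.62 for Vti1a and -2.45 to -1.05 for Cacna2d1. Over the tested probe sets of a gene, log2 changes ran from 2.13 to 2.85 for Cdkn1a, 0.83 to 2.0 for Notch1 and -2.47 to -1.15 for Vti1a.

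**Figure D2:**
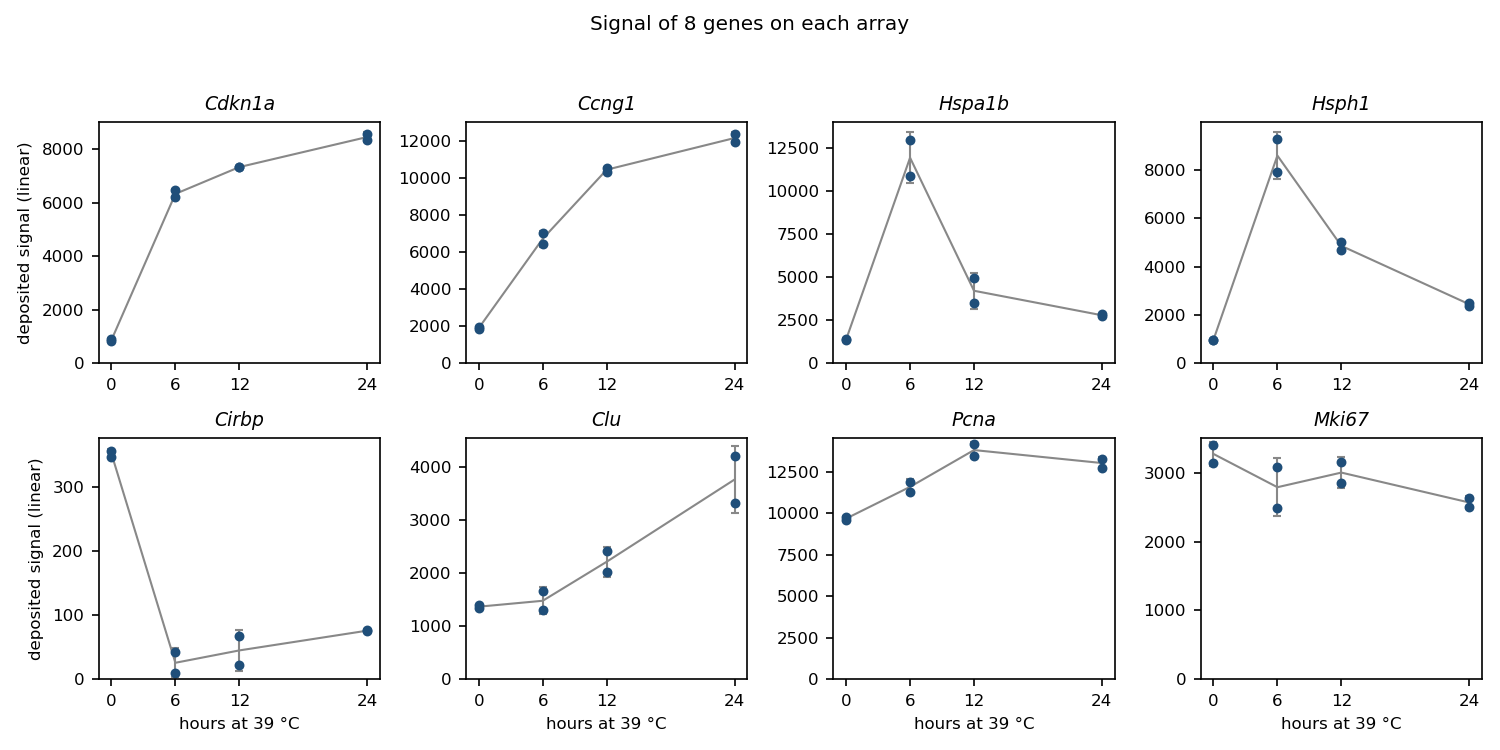
Deposited signal on a linear scale (y axes, each from 0) against hours at 39 °C (x axes) for 8 genes, 1 probe set per gene, with a point per array and a grey line through the means with bars of 1 SD, n = 2 per time. Cdkn1a and Ccng1 stay high to 24 h, Hspa1b and Hsph1 are highest at 6 h, Cirbp is low from 6 h on, and Clu is highest at 24 h.

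At 12 h p53 targets had the largest named rises. Cdkn1a was 8.36-fold above 0 h, from 860.1 ± 73.5 to 7336 ± 16.2 (mean ± SD, n = 2), Trp53inp1, a p53-induced nuclear protein gene, 8.2-fold, Ccng1 7.86-fold and Mdm2 4.93-fold. Ephx1 rose from 1213 ± 73 to 6292 ± 274, and Hsph1 was 4.96-fold above 0 h. Ccn2, the connective tissue growth factor gene, fell 4.81-fold, from 2597 ± 15 to 522 ± 11, and genes of ribosome biogenesis fell as a group.

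Of 3257 probe sets called, 1646 were higher and 1611 lower, and 263 rose and 149 fell at least 2-fold. Other large rises on the log2 scale were Notch1 (2.54 ± 0.17), Dglucy (2.38 ± 0.23), Pnrc1 (2.16 ± 0.10) and Ddit4 (2.13 ± 0.12). Large falls were H1f2 (-2.72 ± 0.20), Cirbp (-2.58 ± 0.38), Cacna2d1 (-2.17 ± 0.39), Gna13 (-2.05 ± 0.15), Nbl1 (-1.92 ± 0.30), Eif2s3y (-1.88 ± 0.15), Fstl1 (-1.80 ± 0.11), Ugcg (-1.77 ± 0.14) and Ncl (-1.73 ± 0.16). Ugcg encodes glucosylceramide synthase and Ncl the nucleolar protein nucleolin. The 6 probe sets of Gna13 ranged from -2.05 to 0.11, with 0 called in the opposite direction.

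Of the p53 target list, 21 of 30 rose, 0 fell and 9 did not pass, or 22 and 1 adjusted over the list alone (camera adjusted p = 3.41e-16, adjusted p = 0.0169 with an estimated correlation). The ribosome biogenesis and MYC target list fell: 1 of 61 rose, 38 fell and 22 did not pass, or 2 and 42 adjusted over the list alone (camera adjusted p = 4.92e-14, adjusted p = 0.0445 with an estimated correlation). The ribosome assembly factor genes Wdr12 (-1.07 ± 0.16) and Wdr43 (-1.03 ± 0.13) and Polr1b (-1.12 ± 0.15), a subunit gene of RNA polymerase I, fell on the log2 scale. DNA replication genes rose at this time: 25 of 60 rose, 5 fell and 30 did not pass, or 26 and 5 adjusted over the list alone (camera adjusted p = 9.41e-05, adjusted p = 0.0445 with an estimated correlation). Cdc6, a replication licensing factor gene, had a log2 change of 1.0 ± 0.13, the mismatch repair gene Msh6 of 0.85 ± 0.10 and Pcna of 0.51 ± 0.09. The origin recognition gene Orc2 fell (-0.62 ± 0.14, adjusted p = 0.111 without 0 h replicate 1 and 0.0798 without 12 h replicate 2). Mitosis genes were not called as a list: 11 of 68 rose, 3 fell and 54 did not pass, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.102, but adjusted p = 0.0451 with only the 2 times compared, 0.0345 without 12 h replicate 2 and 0.0242 by fry). Mki67 had a log2 change of -0.12 ± 0.12 (adjusted p = 0.47).

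Heat shock genes were raised at 12 h: 18 of 37 rose, 5 fell and 14 did not pass, or 21 and 6 adjusted over the list alone (camera adjusted p = 9.41e-05, adjusted p = 0.0599 with an estimated correlation). On the log2 scale Hspa1b was at 1.58 ± 0.15 and Hsp90aa1 was higher too (0.48 ± 0.10, adjusted p = 0.0591 without 0 h replicate 1, 0.0551 without 0 h replicate 2 and 0.0542 without 12 h replicate 1). ER stress genes were higher: 19 of 40 rose, 4 fell and 17 did not pass, or 22 and 6 adjusted over the list alone (camera adjusted p = 9.41e-05, adjusted p = 0.0445 with an estimated correlation). Cholesterol synthesis genes were lower: 1 of 26 rose, 11 fell and 14 did not pass, or 2 and 11 adjusted over the list alone (camera adjusted p = 4.99e-05, adjusted p = 0.0445 with an estimated correlation), with Sqle at -0.93 ± 0.10. Clu rose from 1366 ± 40.9 to 2213 ± 282 (0.68 ± 0.15, adjusted p = 0.0564 without 0 h replicate 2 and 0.0562 without 12 h replicate 1).

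A further 9 lists were called at 12 h with the preset correlation but not with an estimated one. Upward was interferon response: 10 of 27 rose, 0 fell and 17 did not pass, or 11 and 0 adjusted over the list alone (camera adjusted p = 0.000657, adjusted p = 0.0812 with an estimated correlation). For circadian and growth arrest genes, 11 of 33 rose, 1 fell and 21 did not pass, or 12 and 1 adjusted over the list alone (camera adjusted p = 0.00279, adjusted p = 0.161 with an estimated correlation). Lysosome genes rose: 13 of 44 rose, 2 fell and 29 did not pass, or 15 and 4 adjusted over the list alone (camera adjusted p = 0.012, adjusted p = 0.287 with an estimated correlation). For oxidative phosphorylation, 10 of 59 rose, 1 fell and 48 did not pass, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.00338, adjusted p = 0.428 with an estimated correlation). Secreted inflammatory and senescence factors rose: 8 of 27 rose, 2 fell and 17 did not pass, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.0382, adjusted p = 0.382 with an estimated correlation), and were not called at adjusted p = 0.138 without a filter, 0.0592 with the stricter filter, 0.0861 with only the 2 times compared and 0.0546 without 0 h replicate 1. Ribosomal proteins rose: 7 of 42 rose, 0 fell and 35 did not pass, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.000219, adjusted p = 0.422 with an estimated correlation), with adjusted p = 0.491 after quantile normalization. Downward were smooth muscle markers: 0 of 15 rose, 8 fell and 7 did not pass, or 0 and 8 adjusted over the list alone (camera adjusted p = 0.00185, adjusted p = 0.0812 with an estimated correlation). TGF-beta and BMP targets fell: 1 of 26 rose, 8 fell and 17 did not pass, or 3 and 9 adjusted over the list alone (camera adjusted p = 0.0238, adjusted p = 0.128 with an estimated correlation). Immediate early genes fell: 6 of 40 rose, 12 fell and 22 did not pass, or 8 and 15 adjusted over the list alone (camera adjusted p = 0.0276, adjusted p = 0.128 with an estimated correlation), with adjusted p = 0.0816 with the stricter filter.

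Among probe sets called at 12 h, 50.5% were higher, and 40.4% with each array centred on its median (1317 higher and 1943 lower). Their number was 1523 without 0 h replicate 1, 1587 without 0 h replicate 2 and 2084 without 12 h replicate 2. Over the alternatives, among them other offsets, log2 changes ran from -3.09 to -1.83 for Cirbp, -2.37 to -1.36 for Cacna2d1 and -2.65 to -1.19 for Nbl1. The Cirbp range does not include the fit without an offset. Over the tested probe sets of a gene, log2 changes ran from 2.28 to 2.98 for Ccng1, 1.63 to 2.54 for Notch1, -2.72 to -2.11 for H1f2 and -1.77 to -0.91 for Ugcg. In the same way they ran from -1.73 to -0.51 for Ncl, -1.07 to -0.08 for Wdr12 and -0.74 to -0.10 for Orc2.

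After 24 h the p53 targets stood further above 0 h than at 6 h (median log2 difference 0.50, camera adjusted p = 9.67e-08, adjusted p = 0.0276 with an estimated correlation), and ribosome biogenesis genes were lower than at 0 h. Trp53inp1 rose 14.7-fold and Cdkn1a 9.63-fold, from 860.1 ± 73.5 to 8462 ± 170.0 (mean ± SD, n = 2). Krt13, a keratin gene of stratified epithelia, rose from 28 ± 0.212 to 512 ± 68.4, with 0 h near the offset of 21.9 units, and the chemokine gene Cxcl15 from 42.3 ± 11 to 510.1 ± 13. Over the alternatives their log2 changes ran from 2.47 to 4.18 and from 2.29 to 3.62. Ccn2 fell 5.44-fold, from 2597 ± 15 to 459.8 ± 25.1, and the amino acid transporter gene Slc7a5 4.03-fold. Clu rose 2.71-fold, from 1366 ± 40.9 to 3764 ± 624.

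The comparison called 4472 probe sets, 2326 higher and 2146 lower, with 502 rising and 237 falling at least 2-fold. Other large rises were Mmp10 (3.07 ± 0.17), Ddit4 (2.97 ± 0.12), Pnrc1 (2.95 ± 0.10), Notch1 (2.94 ± 0.17), Dglucy (2.93 ± 0.23) and Ephx1 (2.92 ± 0.09) on the log2 scale, where Mmp10 encodes stromelysin 2. Large falls were H1f2 (-2.31 ± 0.14), Tlk2 (-2.03 ± 0.19), Txnrd3 (-1.96 ± 0.21), Cirbp (-1.94 ± 0.38), Fabp5 (-1.86 ± 0.11), Tafa5 (-1.84 ± 0.15), Snx6 (-1.83 ± 0.24) and Myo1c (-1.82 ± 0.18). Fabp5 encodes a fatty acid binding protein and Myo1c an unconventional myosin. The probe sets of Tlk2 ranged from -2.03 to 0.25 and those of Snx6 from -1.83 to 0.10, with 0 and 0 called in the opposite direction.

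Of the p53 target list, 23 of 30 rose, 1 fell and 6 did not pass, or 23 and 1 adjusted over the list alone (camera adjusted p = 1.73e-16, adjusted p = 0.0169 with an estimated correlation). Mdm2 rose by 2.50 ± 0.10 and Ccng1 by 2.67 ± 0.09 on the log2 scale. This Ccng1 value is from its brightest probe set, which was at 1.82 at 6 h and whose signal rose from each time to the next. The Ccng1 changes given above at 6 and 12 h are from other probe sets, so they do not show a fall after 12 h. The ribosome biogenesis and MYC target list fell: 1 of 61 rose, 50 fell and 10 did not pass, or 1 and 54 adjusted over the list alone (camera adjusted p = 7.98e-22, adjusted p = 0.0478 with an estimated correlation). It was lower than at 6 h, with a median log2 difference of -0.64 (camera adjusted p = 8.13e-24, adjusted p = 0.0276 with an estimated correlation). Rrp9 (-1.49 ± 0.15), Wdr43 (-1.32 ± 0.13), Wdr12 (-1.28 ± 0.16) and Polr1b (-1.26 ± 0.15) had the largest falls among its called members. Of the 27 lists, these 2 were called at 24 h with an estimated correlation.

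With the preset correlation, mitosis genes fell: 1 of 68 rose, 22 fell and 45 did not pass, or 1 and 23 adjusted over the list alone (camera adjusted p = 7.74e-05, adjusted p = 0.0619 with an estimated correlation). Trip13 (-1.06 ± 0.12), Kif23 (-0.96 ± 0.20), the transcription factor gene Foxm1 (-0.90 ± 0.14) and the mitotic kinase gene Plk1 (-0.82 ± 0.14) fell most among called members. Mki67 was lower at adjusted p = 0.0386 (-0.35 ± 0.12, adjusted p = 0.0535 after quantile normalization, 0.069 without a filter, 0.0914 without the variance trend, 0.0977 without 0 h replicate 1, 0.212 without 0 h replicate 2, 0.101 without 24 h replicate 1 and 0.186 without 24 h replicate 2). DNA replication genes were higher: 23 of 60 rose, 6 fell and 31 did not pass, or 24 and 7 adjusted over the list alone (camera adjusted p = 0.018, adjusted p = 0.0959 with an estimated correlation). Msh6 was at 0.97 ± 0.10, Cdc6 at 0.89 ± 0.13 and Pcna at 0.43 ± 0.09 on the log2 scale. Ccne2, encoding cyclin E2, was higher (0.90 ± 0.24, adjusted p = 0.0866 without 0 h replicate 2 and 0.114 without 24 h replicate 2) and Orc2 lower (-0.94 ± 0.14).

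Interferon response genes rose: 17 of 27 rose, 0 fell and 10 did not pass, or 18 and 0 adjusted over the list alone (camera adjusted p = 1.11e-06, adjusted p = 0.0619 with an estimated correlation). The antigen peptide transporter genes Tap1 (1.40 ± 0.19) and Tap2 (1.32 ± 0.18), Trim21 (1.49 ± 0.20) and Ifitm3 (1.24 ± 0.11) rose on the log2 scale. Of the circadian and growth arrest list, 20 of 33 rose, 0 fell and 13 did not pass, or 20 and 0 adjusted over the list alone (camera adjusted p = 2.74e-07, adjusted p = 0.0619 with an estimated correlation). The transcription factor genes Cebpd (2.29 ± 0.16) and Foxo3 (1.88 ± 0.27), the MAX partner gene Mxd4 (1.91 ± 0.12) and the cyclin G2 gene Ccng2 (1.76 ± 0.12) rose most among called members. Lysosome genes rose too: 24 of 44 rose, 1 fell and 19 did not pass, or 28 and 2 adjusted over the list alone (camera adjusted p = 1.11e-06, adjusted p = 0.0959 with an estimated correlation). Among them were the hydrolase genes Hexa (1.27 ± 0.11), Tpp1 (1.21 ± 0.09), Idua (1.16 ± 0.23) and Ctsd (0.99 ± 0.10).

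ER stress genes were raised: 23 of 40 rose, 8 fell and 9 did not pass, or 24 and 8 adjusted over the list alone (camera adjusted p = 0.00144, adjusted p = 0.0619 with an estimated correlation). Sdf2l1 was at 1.79 ± 0.11, Pdia4 at 1.40 ± 0.20 and Sesn2, a sestrin gene, at 1.38 ± 0.28 on the log2 scale. Secreted inflammatory and senescence factors were called upward: 11 of 27 rose, 4 fell and 12 did not pass, or 12 and 4 adjusted over the list alone (camera adjusted p = 0.0285, adjusted p = 0.348 with an estimated correlation). That call ended with adjusted p = 0.0668 without a filter and 0.0539 without 24 h replicate 1. Besides Mmp10, the collagenase gene Mmp13 (2.67 ± 0.15) and the adhesion molecule gene Vcam1 (2.30 ± 0.14) rose, and the urokinase receptor gene Plaur (-1.39 ± 0.11) fell. Peritubular myoid and smooth muscle markers were called downward: 1 of 15 rose, 7 fell and 7 did not pass, or 1 and 8 adjusted over the list alone (camera adjusted p = 0.0147, adjusted p = 0.115 with an estimated correlation). The actin-binding protein genes Cnn2 (-1.06 ± 0.09), Flna (-0.68 ± 0.10) and Tpm2 (-0.58 ± 0.12) were lower, and the myosin light chain kinase gene Mylk (0.74 ± 0.22, adjusted p = 0.0756 without a filter, 0.108 without 0 h replicate 1, 0.104 without 0 h replicate 2, 0.136 without 24 h replicate 1 and 0.0907 without 24 h replicate 2) was higher.

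The Sertoli cell marker list was not called at 24 h: 7 of 24 rose, 2 fell and 15 did not pass, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.454). Single members did change: on the log2 scale, besides Clu, the ceruloplasmin gene Cp was at 1.92 ± 0.32 and the inhibin beta A gene Inhba lower (-1.0 ± 0.27, adjusted p = 0.105 without 0 h replicate 1 and 0.123 without 24 h replicate 1). Cp was at 1.20 without 0 h replicate 1 and at 2.64 without 0 h replicate 2. The 6 probe sets of Cp ranged from 0.34 to 2.10 at 24 h. Steroidogenic Leydig cell markers were not called: 3 of 7 rose, 0 fell and 4 did not pass, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.251, but adjusted p = 0.0012 by fry). Star, which encodes the mitochondrial cholesterol carrier of steroidogenesis, was at 1.18 ± 0.24 and the mitochondrial translocator gene Tspo at 0.63 ± 0.09. The third was Nr4a1 (0.48 ± 0.13, adjusted p = 0.0833 without 0 h replicate 1, 0.0754 without 0 h replicate 2, 0.0566 without 24 h replicate 1 and 0.111 without 24 h replicate 2).

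Few markers of germ, blood and endothelial cells were bright enough to be tested. Of the germ cell markers, 1 of 5 rose, 1 fell and 3 did not pass, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.996). The receptor gene Kit (1.96 ± 0.17) was higher and the kinase gene Haspin (-0.77 ± 0.15) lower. For macrophage and blood cell markers, 1 of 5 rose, 0 fell and 4 did not pass, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.744). The risen one was Cd68 (0.59 ± 0.18, adjusted p = 0.0617 after quantile normalization, 0.0677 with median-centred arrays, 0.0779 without a filter, 0.221 without 0 h replicate 1, 0.153 without 24 h replicate 1 and 0.0981 without 24 h replicate 2). Among endothelial markers limma called 0 of 5, and 0 adjusted over the list alone, with 0 below an unadjusted p of 0.05 (camera adjusted p = 0.996). The brightest were Flt4 (-0.22 ± 0.20) and Egfl7 (0.29 ± 0.19).

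The heat shock list was not called at 24 h: 10 of 37 rose, 12 fell and 15 did not pass, or 12 and 13 adjusted over the list alone (camera adjusted p = 0.996). Its median log2 change was 0.04, and -0.06 with median-centred arrays. Hspa1a (1.02 ± 0.14), Dnajb2 (1.15 ± 0.15) and Cryab (1.08 ± 0.11) were higher than at 0 h. Hspa1b was 2.02-fold and Hsph1 2.5-fold above 0 h, and Hsp90aa1 had a log2 change of 0.08 ± 0.10 (adjusted p = 0.604). The Hspa1b value is from its brightest probe set, on which the log2 change at 6 h was 3.10. Cholesterol synthesis was not called either: 4 of 26 rose, 7 fell and 15 did not pass, or 5 and 10 adjusted over the list alone (camera adjusted p = 0.447, but adjusted p = 0.033 by fry). Sqle (-0.89 ± 0.10), Mvk (-0.68 ± 0.17, adjusted p = 0.0981 without 0 h replicate 2 and 0.0761 without 24 h replicate 2) and Lss (-0.64 ± 0.12) fell, and the desaturase gene Scd2 (0.55 ± 0.10) rose. Cell junction genes went both ways: 4 of 23 rose, 4 fell and 15 did not pass, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.996). The connexin gene Gjb2 (1.19 ± 0.24), F11r (0.57 ± 0.10) and the plakoglobin gene Jup (1.14 ± 0.13) were higher and N-cadherin, Cdh2 (-0.71 ± 0.11), lower. Extracellular matrix genes also went both ways: 12 of 47 rose, 8 fell and 27 did not pass, or 12 and 8 adjusted over the list alone (camera adjusted p = 0.562). Decorin, Dcn (2.0 ± 0.11), rose and the metalloproteinase inhibitor gene Timp1 (-1.51 ± 0.11) fell.

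Immediate early genes went both ways at 24 h: 12 of 40 rose, 9 fell and 19 did not pass, or 13 and 10 adjusted over the list alone (camera adjusted p = 0.996). The antiproliferative genes Btg2 (2.08 ± 0.14) and Btg1 (1.40 ± 0.13) were higher and the matrix protein gene Ccn1 (-1.30 ± 0.11) lower. For NRF2 oxidative stress genes, 12 of 29 rose, 7 fell and 10 did not pass, or 12 and 9 adjusted over the list alone (camera adjusted p = 0.263, but adjusted p = 0.000335 by fry). Malic enzyme, Me1 (0.94 ± 0.09), rose, and the transporter gene Abcc1 (-1.03 ± 0.14) and the quinone reductase gene Nqo1 (-0.91 ± 0.20) fell. Of TGF-beta and BMP targets, 5 of 26 rose, 11 fell and 10 did not pass, or 5 and 11 adjusted over the list alone (camera adjusted p = 0.0966, but adjusted p = 0.0152 with the stricter filter and 0.0014 by fry). Id2 (-1.10 ± 0.13) and Smad6 (-1.01 ± 0.16) were lower. Of histone genes, 1 of 8 rose, 4 fell and 3 did not pass, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.0741, but adjusted p = 0.0317 without a filter, 0.0486 without 0 h replicate 2 and 0.000532 by fry). H1f10 (-0.79 ± 0.13) and H2ax (-0.55 ± 0.10) were lower and H2az2 (0.63 ± 0.10) higher.

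Oxidative phosphorylation genes were not called at 24 h: 9 of 59 rose, 9 fell and 41 did not pass, or 9 and 9 adjusted over the list alone (camera adjusted p = 0.996). Ndufb2 (0.71 ± 0.09) and Atp5e (0.65 ± 0.10) were higher, and Ndufb8 (-0.53 ± 0.15, adjusted p = 0.0555 without the variance trend, 0.0704 without 0 h replicate 1, 0.112 without 0 h replicate 2 and 0.163 without 24 h replicate 2) and Cyc1 (-0.49 ± 0.10) lower. Not called either were ribosomal proteins: 1 of 42 rose, 1 fell and 40 did not pass, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.942). There Rps25 was at -1.33 ± 0.10 and Rpl14 higher (0.54 ± 0.13, adjusted p = 0.077 without 0 h replicate 2 and 0.0904 without 24 h replicate 1). For glycolysis and lactate, 3 of 21 rose, 3 fell and 15 did not pass, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.996), with the phosphofructokinase gene Pfkl (1.07 ± 0.11) and Bnip3 (0.72 ± 0.14) higher. The phosphofructokinase gene Pfkp (-0.53 ± 0.17, adjusted p = 0.0825 without a filter, 0.0571 without 0 h replicate 1, 0.217 without 0 h replicate 2, 0.0617 without 24 h replicate 1 and 0.196 without 24 h replicate 2) and Ndrg1 (-0.53 ± 0.15, adjusted p = 0.122 without 0 h replicate 2, 0.103 without 24 h replicate 1 and 0.053 without 24 h replicate 2) were lower. Of the reference genes, 2 of 14 rose, 3 fell and 9 did not pass, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.996). B2m, the MHC class I light chain gene, was at 0.95 ± 0.12 and the transferrin receptor gene Tfrc at -0.49 ± 0.09. Pgk1 (-0.41 ± 0.12, adjusted p = 0.0709 without a filter, 0.0725 without the variance trend, 0.15 without 0 h replicate 1, 0.0899 without 0 h replicate 2 and 0.206 without 24 h replicate 2) and Ywhaz (-0.38 ± 0.09, adjusted p = 0.0571 without 0 h replicate 1, 0.0713 without 0 h replicate 2 and 0.0797 without 24 h replicate 2) were lower. Of 7 Ywhaz probe sets, 1 was called in the opposite direction, and the highest log2 change was 0.48.

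Among probe sets called at 24 h, 52% were higher, against 37.5% with each array centred on its median (1721 higher and 2865 lower). That moved the median log2 change of all tested probe sets from 0.016 to -0.088. Their number was 2595 without 0 h replicate 1, 2697 without 0 h replicate 2, 2790 without 24 h replicate 1 and 2678 without 24 h replicate 2. Median, mean and camera direction differed in sign for 3 lists at 6 h, 3 at 12 h and 6 at 24 h, 0 of them called. At 6 h these were extracellular matrix, NRF2 oxidative stress and circadian and growth arrest. At 12 h they were extracellular matrix, germ cell markers and macrophage and blood cell markers, and at 24 h cytosolic heat shock, cell junctions, glycolysis and lactate, oxidative phosphorylation, ribosomal proteins and immediate early genes. Over the alternatives, among them other offsets, log2 changes ran from 2.47 to 3.44 for Mmp10. Over the tested probe sets of a gene, log2 changes ran from 1.97 to 2.94 for Notch1, -1.84 to -0.74 for Tafa5, -1.82 to -0.91 for Myo1c and -1.28 to 0.07 for Wdr12. In the same way they ran from -1.01 to -0.30 for Orc2, 0.85 to 1.49 for Trim21, 0.24 to 1.91 for Mxd4 and 0.57 to 1.21 for Tpp1. They also ran from 1.38 to 2.19 for Sesn2, 1.30 to 2.30 for Vcam1 and 1.18 to 2.06 for Star.

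**Figure D3:**
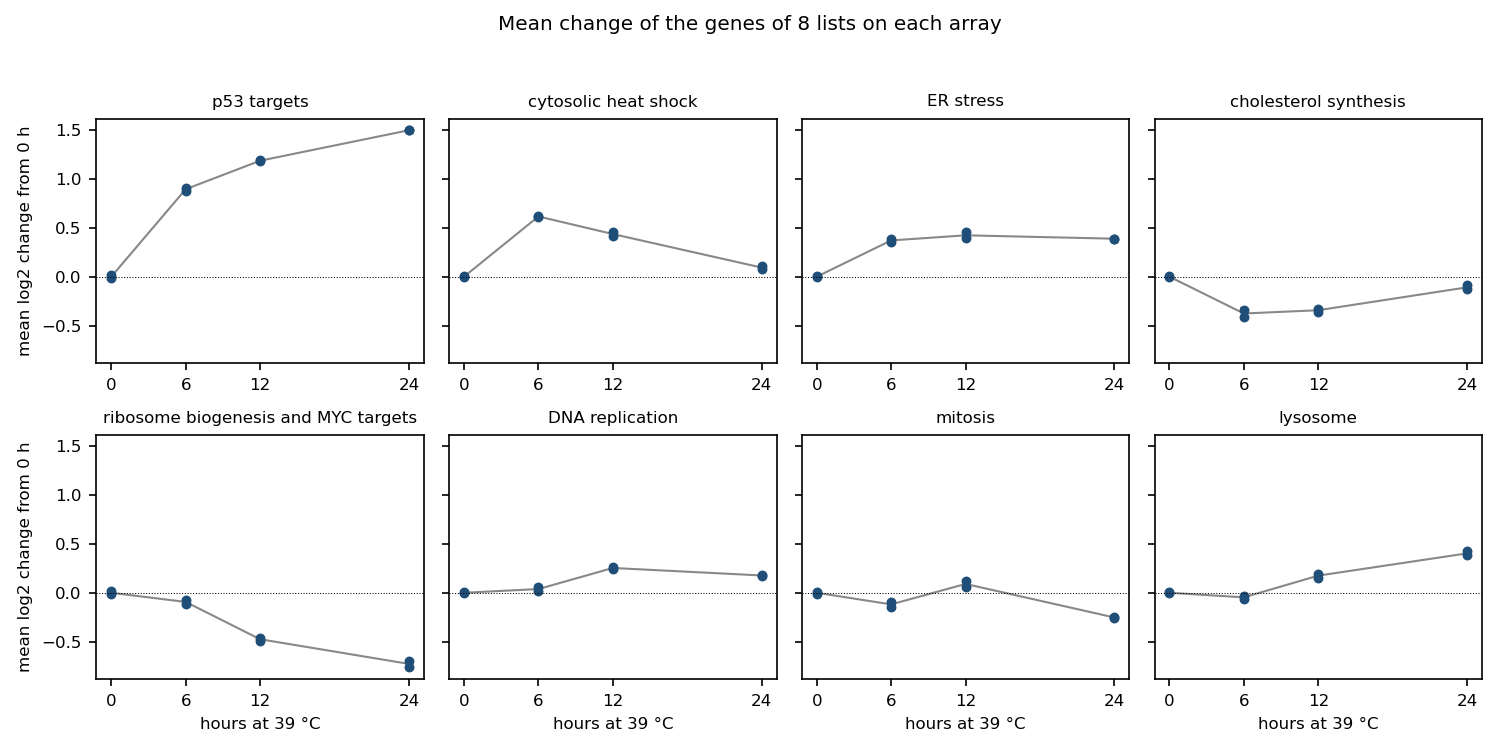
Mean log2 change from the 0 h mean over the tested genes of 8 lists (y axes, shared) against hours at 39 °C (x axes), with a point per array and a grey line through the means with bars of 1 SD, n = 2 per time. The p53 targets have a mean of 1.49 at 24 h, the cytosolic heat shock list of 0.61 at 6 h, and ribosome biogenesis and MYC targets of -0.73 at 24 h.

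Comparing the later times with each other asked whether the change from 0 h itself changed. From 6 to 12 h the Hsp70 genes fell back: Hspa1a went from 3744 ± 483 to 1004 ± 122 (mean ± SD, n = 2), a 3.67-fold fall, and Hspa1b fell 3.09-fold. Ccn2 fell 2.78-fold and Srsf5 rose 3.14-fold, from 873 ± 96.8 to 2786 ± 106. Cxcl15 (1.82 ± 0.23), the uroplakin gene Upk3b (1.77 ± 0.19), Cmbl (1.74 ± 0.19) and the vomeronasal receptor gene Vmn1r44 (2.36 ± 0.32) rose on the log2 scale. Lce1h (-2.03 ± 0.37) and Ptov1 (-1.54 ± 0.24) fell. In all 1130 probe sets were called, 626 higher and 504 lower. With median-centred arrays it was 448 higher and 535 lower. Over the alternatives, among them other offsets, log2 changes ran from 0.98 to 2.95 for Cxcl15, 1.45 to 2.75 for Vmn1r44 and -2.62 to -1.36 for Lce1h. Over the tested probe sets of a gene, log2 changes ran from -1.54 to 0.08 for Ptov1.

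Mitosis genes rose from 6 to 12 h: 17 of 68 rose, 1 fell and 50 did not pass, or 23 and 2 adjusted over the list alone (camera adjusted p = 7.53e-06, adjusted p = 0.0561 with an estimated correlation). So did DNA replication genes: 10 of 60 rose, 0 fell and 50 did not pass, or 17 and 1 adjusted over the list alone (camera adjusted p = 5.14e-06, adjusted p = 0.0561 with an estimated correlation). The reference gene list was called upward as well, with a median log2 difference of 0.21 against 0.20 for mitosis and 0.21 for DNA replication: 0 of 14 rose, 0 fell and 14 did not pass, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0124, adjusted p = 0.368 with an estimated correlation). It stayed called, at 0.12 after quantile normalization (adjusted p = 0.0367) and 0.17 with median-centred arrays (adjusted p = 0.0262). Ribosome biogenesis and MYC targets fell: 0 of 61 rose, 25 fell and 36 did not pass, or 0 and 38 adjusted over the list alone (camera adjusted p = 4.09e-18, adjusted p = 0.0561 with an estimated correlation). In the heat shock list, 0 of 37 rose, 7 fell and 30 did not pass, or 2 and 8 adjusted over the list alone (camera adjusted p = 0.00114, adjusted p = 0.103 with an estimated correlation). The p53 targets list was called upward (median log2 difference 0.33, 9 risen and 0 fallen of 30, camera adjusted p = 3.32e-05, adjusted p = 0.0561 with an estimated correlation). The interferon response list was called upward (median log2 difference 0.35, 4 risen and 0 fallen of 27, camera adjusted p = 0.000526, adjusted p = 0.103 with an estimated correlation). The lysosome list was called upward (median log2 difference 0.21, 10 risen and 0 fallen of 44, camera adjusted p = 8.63e-05, adjusted p = 0.136 with an estimated correlation). The glycolysis and lactate list was called upward (median log2 difference 0.17, 4 risen and 0 fallen of 21, camera adjusted p = 0.0132, adjusted p = 0.379 with an estimated correlation). The circadian and growth arrest list was called upward (median log2 difference 0.24, 7 risen and 0 fallen of 33, camera adjusted p = 8.63e-05, adjusted p = 0.103 with an estimated correlation). The peritubular myoid and smooth muscle markers list was called downward (median log2 difference -0.12, 0 risen and 4 fallen of 15, camera adjusted p = 0.0043, adjusted p = 0.103 with an estimated correlation). The number of called probe sets was 240 with only the 4 arrays of these times, 644 without a filter and 606 without the variance trend. It was 484 without 12 h replicate 1 and 330 without 12 h replicate 2. Arrays of the other times moved it to 592 without 0 h replicate 1, 592 without 0 h replicate 2, 701 without 24 h replicate 1 and 706 without 24 h replicate 2.

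From 12 to 24 h the ceruloplasmin gene Cp went from 229 ± 24 to 1305 ± 189 (mean ± SD, n = 2), 5.27-fold, decorin from 1435 ± 44.5 to 5848 ± 602, 4.02-fold, and Cxcl15 rose 4.31-fold. Star (1.98 ± 0.29, adjusted p = 0.0555 without 24 h replicate 2) and Clu (0.76 ± 0.15, adjusted p = 0.0595 without the variance trend, 0.0941 without 12 h replicate 2 and 0.13 without 24 h replicate 1) rose on the log2 scale. These Cp signals and this Star change are from other probe sets than the Cp and Star changes from 0 h given above. On the brightest Cp probe set the log2 change from 0 h was 0.78 ± 0.32 at 12 h (adjusted p = 0.103) and 1.92 ± 0.32 at 24 h. The values above therefore do not show a fall of Cp or Star below 0 h at 12 h. The ribosomal protein gene Rps25 fell 2.41-fold. Faap20 rose (1.74 ± 0.42, adjusted p = 0.0938 without a filter, 0.0883 without the variance trend, 0.0533 without 0 h replicate 1, 0.054 without 0 h replicate 2, 0.0661 without 12 h replicate 1, 0.165 without 12 h replicate 2, 0.211 without 24 h replicate 1 and 0.108 without 24 h replicate 2). Nts, the neurotensin gene, fell (-1.47 ± 0.31, adjusted p = 0.0591 without a filter, 0.117 without 12 h replicate 2, 0.147 without 24 h replicate 1 and 0.0518 without 24 h replicate 2), as did Ppp1r3f (-1.31 ± 0.28, adjusted p = 0.0655 without a filter, 0.129 without 12 h replicate 2, 0.141 without 24 h replicate 1 and 0.0981 without 24 h replicate 2). The serine hydroxymethyltransferase gene Shmt2 fell (-1.25 ± 0.24, adjusted p = 0.0757 without 12 h replicate 1, 0.082 without 24 h replicate 1 and 0.0938 without 24 h replicate 2), and so did the mitotic activator gene Cdc20 (-1.21 ± 0.21, adjusted p = 0.0599 without 12 h replicate 1, 0.0713 without 24 h replicate 1 and 0.0717 without 24 h replicate 2). Over the tested probe sets of a gene, log2 changes ran from 1.14 to 2.40 for Cp, 1.05 to 1.98 for Star, -0.03 to 1.74 for Faap20 and -1.25 to -0.24 for Shmt2. In the same way they ran from -1.21 to -0.42 for Cdc20.

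Mitosis genes fell from 12 to 24 h: 0 of 68 rose, 24 fell and 44 did not pass, or 0 and 36 adjusted over the list alone (camera adjusted p = 5.86e-17, adjusted p = 0.0267 with an estimated correlation). The heat shock list fell as well: 0 of 37 rose, 14 fell and 23 did not pass, or 1 and 21 adjusted over the list alone (camera adjusted p = 6.63e-12, adjusted p = 0.0294 with an estimated correlation). The p53 targets rose: 7 of 30 rose, 0 fell and 23 did not pass, or 9 and 0 adjusted over the list alone (camera adjusted p = 2.23e-06, adjusted p = 0.0427 with an estimated correlation). The cell junctions list was called upward (median log2 difference 0.13, 2 risen and 0 fallen of 23, camera adjusted p = 0.0356, adjusted p = 0.204 with an estimated correlation), with a median of 0.08 with median-centred arrays (adjusted p = 0.0357). The interferon response list was called upward (median log2 difference 0.29, 5 risen and 0 fallen of 27, camera adjusted p = 4.72e-05, adjusted p = 0.0583 with an estimated correlation). The cholesterol synthesis list was called upward (median log2 difference 0.20, 7 risen and 0 fallen of 26, camera adjusted p = 2.52e-05, adjusted p = 0.0523 with an estimated correlation). The steroidogenic Leydig cell markers list was called upward (median log2 difference 0.25, 1 risen and 0 fallen of 7, camera adjusted p = 0.0463, adjusted p = 0.176 with an estimated correlation), with a median of 0.21 after quantile normalization (adjusted p = 0.0557). The lysosome list was called upward (median log2 difference 0.27, 6 risen and 0 fallen of 44, camera adjusted p = 5.49e-07, adjusted p = 0.0711 with an estimated correlation). The immediate early genes list was called upward (median log2 difference 0.21, 7 risen and 1 fallen of 40, camera adjusted p = 0.000888, adjusted p = 0.0583 with an estimated correlation). The circadian and growth arrest list was called upward (median log2 difference 0.27, 11 risen and 0 fallen of 33, camera adjusted p = 1.68e-06, adjusted p = 0.0593 with an estimated correlation). The oxidative phosphorylation list was called downward (median log2 difference -0.13, 0 risen and 4 fallen of 59, camera adjusted p = 2.54e-05, adjusted p = 0.251 with an estimated correlation), with a median of -0.05 after quantile normalization (adjusted p = 0.11). The ribosome biogenesis and MYC targets list was called downward (median log2 difference -0.26, 0 risen and 9 fallen of 61, camera adjusted p = 6.04e-12, adjusted p = 0.0583 with an estimated correlation). The ribosomal proteins list was called downward (median log2 difference -0.25, 1 risen and 3 fallen of 42, camera adjusted p = 7.58e-09, adjusted p = 0.204 with an estimated correlation), with a median of -0.04 after quantile normalization (adjusted p = 0.218). Of 934 probe sets called, 512 were higher and 422 lower. The share higher was 54.8%, and 42.2% with median-centred arrays (373 higher and 510 lower). The number called was 529 without a filter and 369 without the variance trend. It was 142 without 24 h replicate 1, 84 without 24 h replicate 2, 318 without 12 h replicate 1 and 219 without 12 h replicate 2. Arrays of the other times also moved it, to 474 without 0 h replicate 1, 488 without 0 h replicate 2, 1636 without 6 h replicate 1 and 1645 without 6 h replicate 2.

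Between 6 and 24 h, Cxcl15 rose from 13.1 ± 1.48 to 510.1 ± 13 (mean ± SD, n = 2), and the retinal reductase gene Dhrs3 7.14-fold. The 6 h signal of Cxcl15 was below the offset of 21.9 units, and over the alternatives its log2 change ran from 2.68 to 5.28. The aldehyde dehydrogenase gene Aldh3a1 (2.68 ± 0.14), Krt13 (2.62 ± 0.24) and the complement gene C1s1 (2.56 ± 0.21) rose on the log2 scale. Hspa1a (-2.58 ± 0.14), Hspa1b (-2.15 ± 0.11), Lce1h (-2.47 ± 0.37), the cardiac troponin gene Tnnt2 (-2.22 ± 0.21) and Shmt2 (-2.06 ± 0.24) fell. Among probe sets higher at 6 h than at 0 h, 249 of 1175 were lower at 24 h than at 6 h. Among those lower at 6 h, 423 of 1266 were higher at 24 h. In 20 simulations in which nothing changed between 6 and 24 h, neither count exceeded 1. With no change put in, the adjusted test of 24 h against 6 h calls almost nothing. Low simulated counts thus followed from the setting and add nothing to that test. These drew independent noise for each probe set and array, so they cannot show what an error shared across a 6 h array would give. The 6 h arrays enter both comparisons and were the least alike, with r = 0.9815. In all 3377 probe sets were called between these times, 1847 higher and 1530 lower. The share higher was 54.7%, and 40.5% with median-centred arrays (1402 and 2057). Their number was 1784 without 24 h replicate 1 and 1746 without 24 h replicate 2. Over the alternatives, among them other offsets, log2 changes ran from 2.03 to 2.99 for Krt13, 1.97 to 2.94 for C1s1, -2.70 to -1.61 for Lce1h, -2.67 to -1.60 for Tnnt2 and -2.47 to -1.47 for Shmt2. Over the tested probe sets of a gene, log2 changes ran from -2.22 to -1.50 for Tnnt2 and -2.06 to -0.66 for Shmt2.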

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

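The changes from 0 h at 6 h and at 24 h differed, by the direct test of 24 h against 6 h, for 10 of the 27 gene lists and for 6 of the 8 tested genes that were always to be named, and control probe sets for repeats were brighter at 12 h than at 0 h. The tests of lists between 6 and 24 h were not planned. The difference of a list is the median of its genes' own differences, which is not the difference of the medians at 6 and 24 h. The further tests on the replication and mitosis lists and on the repeats were chosen after these results were seen, as was leaving 3 genes out of the heat shock list.

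The heat shock list had a median log2 change of 0.37 at 6 h and 0.04 at 24 h, and a median per-gene difference of -0.45 (adjusted p = 2.82e-10, 0.0276 with an estimated correlation), with Hspa1b at -2.09 (adjusted p = 6.41e-06) and Hsp90aa1 at -0.47 (adjusted p = 0.00637). Probe sets shared between Hspa1a and Hspa1b could carry such a pattern, but without Hspa1a, Hspa1b and Hsph1 the median per-gene difference was still -0.38 (camera adjusted p = 4.79e-08). A median over 37 genes moves little when these genes are left out, so only the camera test weighs against this. The authors' scaling is also argued against: after quantile normalization the median per-gene difference was -0.35 (camera adjusted p = 1.06e-08). A decline of the heat shock response within 24 h at 39 °C remains a hypothesis, found and tested on the same data. Heat and loss of T-antigen were not separated by the design.

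DNA replication genes rose at 12 h (25 members) while mitosis genes fell at 24 h (22 members, adjusted p = 0.0619 for the list with an estimated correlation); between 6 and 24 h the median per-gene differences were 0.12 (adjusted p = 0.0388, 0.132 with an estimated correlation) and -0.17 (adjusted p = 0.0095, 0.132 with an estimated correlation). The replication difference was 0.13 after quantile normalization (adjusted p = 0.00993) and 0.04 with median-centred arrays (adjusted p = 0.0752), so scaling stays open for it. If scaling were the cause of the changes from 0 h, the gene calls should end with another scaling. After quantile normalization 25 of the 25 replication genes and 20 of the 22 mitosis genes were still called. With median-centred arrays 19 and 22 were. Median centring lowers changes at 24 h (median of all tested probe sets from 0.016 to -0.088), so it could hardly end falls there. At 12 h it moved that median only from 0.0053 to -0.053, against 0.31 for the replication list. These counts therefore weigh only weakly against scaling. The choice of probe set is argued against: other probe sets of these genes moved the same way for 12 of 12 replication genes (exact sign test p = 0.000488) and 10 of 12 mitosis genes (p = 0.0386, exact). The sign test takes the genes as independent, although they share arrays and were picked for their called direction. Its p-values are therefore only descriptive. A cell population with fewer dividing cells that keeps replication transcripts may show this, as a hypothesis; no cell cycle measurement was used here.

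Control probe sets for the short interspersed repeats B1 and B2, which the comparisons leave out, were brighter on both 12 h arrays than on both 0 h arrays, by 0.36 and 0.33 on the log2 scale, and were at -0.04 and 0.02 at 24 h. The 6 h changes were 0.123 and 0.215. There the B2 signal was 34889.9 on replicate 1, above both 12 h arrays, and 23116.5 on replicate 2. A stretch of the bright end of the 12 h arrays is a candidate explanation for the change at 12 h. The B1 change lay at percentile 91.5 and the B2 change at percentile 81.2 of the changes of 224 and 32 other probe sets of similar brightness, and quantile normalization with the controls left 0.21 and 0.05. The median change of those other probe sets at 12 h was 0.15 for B1 and 0.29 for B2. Neither repeat lay outside the range of such probe sets. B1 did not keep rising with time at 39 °C. A passing rise of B1 transcripts at 12 h, gone at 24 h, stays open as an untested explanation.

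The other 7 lists also differed between 6 and 24 h. The p53 target list had a median log2 change of 0.77 at 6 h and 1.53 at 24 h, and a median per-gene difference of 0.50 (adjusted p = 9.67e-08, 0.0276 with an estimated correlation). Interferon response genes differed by 0.55 (adjusted p = 4.25e-07, 0.0481 with an estimated correlation), lysosome genes by 0.43 (adjusted p = 4.14e-09, 0.0635 with an estimated correlation) and circadian and growth arrest genes by 0.54 (adjusted p = 3.83e-08, 0.0598 with an estimated correlation). Cholesterol synthesis genes differed by 0.27 (adjusted p = 0.00441, 0.0916 with an estimated correlation). Ribosome biogenesis and MYC targets had a difference of -0.64 (adjusted p = 8.13e-24, 0.0276 with an estimated correlation), and ribosomal proteins differed by -0.17 (adjusted p = 0.0019, 0.492 with an estimated correlation), but by -0.07 after quantile normalization (adjusted p = 0.297, and 0.0688 by fry without it). Among genes, the differences were 0.42 (adjusted p = 0.00719) for Cdkn1a, 0.54 (adjusted p = 0.00338) for Mdm2, 0.86 (adjusted p = 7.32e-05) for Ccng1 and 1.34 (adjusted p = 0.000103) for Clu. Without 24 h replicate 1 the Cdkn1a and Hsp90aa1 differences were not called, at adjusted p = 0.0637 and 0.0629.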

How the results depend on the processing

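Of the named genes called in any comparison and the lists called against 0 h, 0 genes and 0 lists changed direction under the alternatives run. Some alternatives left called gene results untested. Of 301, 299 were tested after quantile normalization, 293 without an offset, 271 with 1 probe set per gene and 247 with the stricter filter. Untested results are not counted as lost. Of 301 called results of named genes, 6 were lost after quantile normalization, 6 with median-centred arrays, 20 without a filter, 20 without the variance trend, 5 with only the 2 times compared and 49 and 47 without 0 h replicate 1 and 2. Of 30 list calls against 0 h, 19 were lost with an estimated correlation, leaving 4 at 6 h, 5 at 12 h and 2 at 24 h. Fry called 12 lists at 6 h and added 17 calls in all. Signal over background limits dim genes: the filter on the mean over all arrays kept probe sets that were dim at single times.

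With 1 probe set per gene, fewer tests gave 3436 calls for any change, 1524 for 6 h against 0 h, 2071 for 12 h against 0 h, 2842 for 24 h against 0 h, 740 for 12 h against 6 h, 2119 for 24 h against 6 h. From 6 to 12 h the count was 240 with 4 arrays, 644 without a filter and 606 without the trend, and from 12 to 24 h 529 and 369; the cause was not tested. Any change over time was not run with only 4 arrays. With each array left out in turn, counts ranged from 3303 to 6608 for any change, 836 to 3005 for 6 h against 0 h, 1523 to 4148 for 12 h against 0 h, 2595 to 5191 for 24 h against 0 h, 330 to 1552 for 12 h against 6 h, 84 to 1645 for 24 h against 12 h, 1746 to 3827 for 24 h against 6 h, and list calls from 4 to 7 at 6 h, 14 to 16 at 12 h, 9 to 11 at 24 h.

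Deviations of same-numbered samples from their group means correlated by 0.05, 0.15, 0.07, 0.08, 0.18 and 0.08 across probe sets, not all above 0.1, so the numbers were not taken to pair the samples. With the replicate block the counts were 5982 for any change and 2813, 3647, 4832, 1463, 1212, 3761 in the order above, and 0 named genes and 0 lists lost their call.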

Other observations

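The gene lists below were written after the largest changes had been seen, and each was tested again without the genes seen before, with p-values adjusted over these 4 lists, an adjustment added after the results were seen. The list of serine, one-carbon and amino acid synthesis genes also held aminoacyl-tRNA synthetase and amino acid transporter genes. This list fell at 24 h: of 25 tested, 13 fell and 2 rose, with a median log2 change of -0.41. Psat1 (-0.64 ± 0.13), Asns (-1.04 ± 0.11) and Phgdh (-1.10 ± 0.09), enzymes of serine and asparagine synthesis, were named after their values had been seen. Without the 6 genes seen before, 8 of 19 fell and 1 rose (camera adjusted p = 0.0105, adjusted p = 0.194 with an estimated correlation). The rest of the list was thus called downward with the preset correlation only. Those that fell were the tRNA synthetase genes Nars, Gars, Tars and Iars, the transporter gene Slc1a5, and Got1, Psph and Shmt1. Synthesis enzymes beyond the genes seen before were not tested on their own.

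Transcripts of SR proteins and hnRNPs, which bind pre-mRNA, went both ways at 6 h: 8 of 39 fell, Srsf5 and Hnrnpd among them, and 6 rose. Without the 4 genes seen before, 5 of 35 fell and 6 rose at 6 h (camera adjusted p = 0.67), so a fall of the class was not seen at that time. At 24 h 18 of 39 fell and 3 rose, with a median log2 change of -0.25; without those 4 genes 16 of 35 fell (camera adjusted p = 0.0105, adjusted p = 0.128 with an estimated correlation).

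Krt13, Lce1h and Upk3b, genes of stratified and urothelial epithelia, and the complement and acute phase genes C1s1 and Cp were among the largest changes. The whole epithelial list went both ways at 24 h: of 11 tested, 3 rose and 4 fell (camera adjusted p = 0.725). Krt13 (3.412 ± 0.239) and Upk3b (1.988 ± 0.229) were higher and Lce1h (-1.345 ± 0.371) lower. All 3 tested complement genes rose, but C1s1 and Cp had been picked for their rise. The lists were too small to test without the genes seen before, which were 7 epithelial and 2 complement genes. Then 4 epithelial genes remained (camera adjusted p = 0.289) and 1 complement gene (camera adjusted p = 0.204). A change of either class beyond the genes seen before stays open. Warming could lower cold-inducible transcripts, of which Cirbp is one. Rbm3, also induced by cold, was chosen to test this, but 0 tested probe sets named Rbm3 and no other gene, so it stays open.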
